A study of Drosophila melanogaster with 6 samples.

How the data were processed

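The authors deposited one table of TPM values for 15010 genes in 6 libraries, per the file headers, and each library sums to 1000000. TopHat and edgeR are named per the submitters' processing notes, without versions or roles. Genome build, annotation and read counter are not given in the sources used here. RNA was extracted with a Trizol or Tripure protocol and polyA libraries were made with an Illumina kit, per the labels' protocols. The labels and the series description give the tissue as intestine. The marker levels in the report show that the libraries also hold abundant transcripts of the eye, the ovary and other body parts, and no library was removed or relabelled for that reason.

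Columns were assigned to samples by group letter and replicate number. Symbols were matched to the BDGP6.54 annotation by current symbol (11527), older symbol (3330) or older symbol and exon length (96), which left 41 with no identifier and 16 with more than 1. TPM values were whole multiples of the value of 1 read for 14167 genes when the annotated exon length was used (94.7% of those with a length, relative tolerance 1e-06), and the others were solved from other lengths, so reads were recovered for 15010 genes. Overlapping genes can carry the same reads, and whether strand was used in counting is not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. Total recovered reads ranged from 33956907 to 45191935 per library. Floors cover counting error only and were set at 3 reads per library.

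The main test was limma 3.58.1 in R 4.3.3 with an intensity trend on log2(TPM + 1), for genes with at least 1 TPM in at least 3 libraries (10816), with group as the only term and Benjamini-Hochberg adjustment at 0.05. The smallest exact p of 3 against 3 libraries is 0.1. Of 38 gene lists fixed before the data were examined, 35 had at least 5 tested members and were tested with camera (preset correlation 0.01), with an estimated correlation and fry as alternatives. Lists covered digestion, metabolism, insulin signalling, gut cell types, immunity, stress, chromatin, ribosomes and other tissues. A further 5 marker lists (photoreceptor, antenna, flight muscle, oenocyte, oocyte and nurse cell) were chosen after seeing the data and used for levels and medians.

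Named genes followed a rule fixed before the data were examined. It takes InR; 12 genes per direction past the adjusted p with non-overlapping groups by size, filled to 12 by the smallest unadjusted p and then given as values that did not pass; for each list up to 4 members past the adjusted p, or the 2 with the smallest unadjusted p where fewer than 2 pass; and for other-tissue lists also the most abundant 2. Other genes are marked as chosen after their values were seen.

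Alternatives were pseudocounts of 0.1 and 5, no filter, a filter of 5 TPM, median-of-ratios rescaling, quantile normalization, eBayes without trend, robust eBayes, a replicate block and leaving out each library. limma voom on recovered reads (at least 10 reads in at least 3 libraries) was chosen after seeing the data. The gene tests were tested on simulated data over 10816 genes in 5 runs with 200 genes changed in each, which recovered 90.4% of genes changed by 1 log2 unit and 97.0% of those changed by 2, with 9.8 false calls per run. In 100 runs with 4 genes changed in each, 47.5% and 89% were recovered, with 0.35 false calls per run. In the list test over 35 lists, a list moved by design was called in 5 of 5 runs and 1 unmoved list was called in all. All these simulations drew noise independently for each gene from the shrunken variances of the limma fit. They cannot show how the list test behaves where genes vary together, as in the cell cycle list (estimated correlation 0.97). All 10 splits of the 6 libraries into 3 against 3 were refitted.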

Results

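Polyadenylated RNA of adult fruit fly (Drosophila melanogaster) progeny was sequenced in 6 libraries, all of them labelled intestine. The 3 control libraries came from progeny of mothers carrying MTD-GAL4, a driver active in the maternal germline, and the 3 libraries of the other group from progeny of mothers that also expressed InR-DN, a dominant-negative insulin receptor. Both kinds of mother were crossed to Oregon R males, and the comparison asks how gene expression in the progeny differs by maternal genotype. Progeny can inherit the transgene from these mothers. An effect of the perturbed maternal germline therefore cannot be told apart from an effect of an inherited transgene. The values are transcript abundances in TPM, scaled to the same total in each library, for 15010 genes. Whole reads recovered from them summed to 35878878, 45088754 and 45191935 per control library and to 35440525, 42457228 and 33956907 per library of the InR-DN group. The labels do not say whether the libraries of a group came from separate animals or crosses, so p-values measure only the spread between these samples, which may be technical. No pair of libraries within a group agreed within sampling noise, the closest pair having a chi-square per degree of freedom of 21.4 over 12081 genes. The pair furthest apart, InR-DN replicates 1 and 2, had 94.4 over 11899 genes.

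Although the labels name the intestine alone, all 6 libraries held abundant transcripts of other body parts. ninaE, which encodes the main rhodopsin of the photoreceptors of the eye, lay at 2249 to 3015 TPM and ranked number 51 of all genes by mean TPM. Arr2, a photoreceptor arrestin, lay at 807 to 1191 TPM. The oocyte mRNA osk lay at 751 to 866 TPM and nos, also an oocyte mRNA, at 114.9 to 190.2 TPM. Cyp4g1, an oenocyte enzyme of cuticular hydrocarbon synthesis, lay at 6425 to 10139 TPM and ranked number 3. The flight muscle troponin TpnC4 lay at 77.8 to 117 TPM, the olfactory co-receptor Orco at 2.51 to 3.70 TPM. Genes of the gut, also chosen after their values were seen, were abundant too, with the trypsin alphaTry at 4767 to 7517 TPM and the protease yip7 at 4071 to 6479.6 TPM. In contrast, 18 of 20 testis and accessory gland genes lay below 1 TPM in every library. Some markers moved in opposite ways within the InR-DN group. In InR-DN replicates 1 to 3 ninaE lay at 2249, 3015 and 2611 TPM and nos at 190.2, 114.9 and 142.3 TPM. The photoreceptor gene norpA and the oocyte genes grk and orb did not follow these orders. The photoreceptor, antenna, flight muscle, oenocyte and oocyte markers were chosen after their values were seen, and their median log2 fold changes between the groups were -0.06, -0.17, 0.13, -0.36 and 0.03. The values below therefore describe libraries labelled intestine and are not taken as values of intestine alone.

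**Figure D1:**
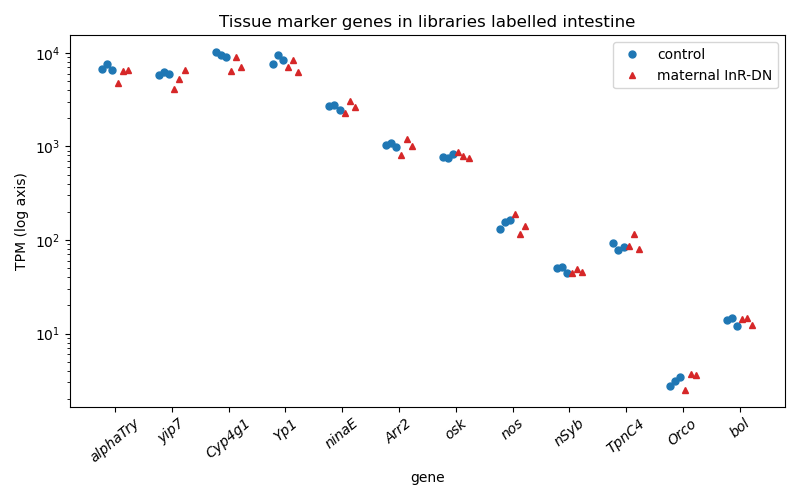
TPM (log axis) of 12 genes in each library; circles are the 3 control libraries and triangles the 3 libraries of progeny of InR-DN mothers. The photoreceptor gene ninaE lay at 2249 to 3015 TPM and the oocyte gene osk at 751 to 866 TPM in libraries labelled intestine.

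InR, the insulin receptor gene (FBgn0283499; arm 3R, 21570248 to 21619321 in the BDGP6.54 annotation), differed by less than the spread between replicates. InR averaged 21.4 ± 0.998 TPM in controls and 20.5 ± 2.11 TPM in progeny of InR-DN mothers (SD, n = 3 per group), a log2 fold change of -0.07 with a standard error of 0.10 in the limma fit (adjusted p = 1.00). These values describe the progeny and are no check of the maternal transgene, whose reads the table does not separate from those of the endogenous gene.

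No gene passed the limma test between progeny of InR-DN mothers and controls at an adjusted p of 0.05, and none therefore at a 2-fold change. Of 10816 genes tested, 341 had an unadjusted p under 0.05, where 541 would be expected by chance, with 122 higher and 219 lower. That count rested on 1 library: without InR-DN replicate 2 it was 937, above the number expected by chance, although 0 genes passed. Leaving out 1 library gave 0 to 3 genes past the adjusted p, with 1 without control replicate 1, 3 without control replicate 2, 1 without InR-DN replicate 1 and 1 without InR-DN replicate 3. The smallest adjusted p was 0.141. The groups did not overlap for 688 genes (6.36%), against a chance share of 10%. In the limma voom fit of recovered reads, 1 gene passed (CG31219, adjusted p = 0.0441) and 353 had an unadjusted p under 0.05. CG31219 also passed with a pseudocount of 0.1 (adjusted p = 0.0153). In simulated data, noise was independent between genes and drawn from the shrunken variances of the limma fit. With 200 of 10816 genes changed at once, calls covered 90.4% of genes changed by 1 log2 unit and 97.0% of those changed by 2. With only 4 changed, which makes the adjustment stricter, the shares were 47.5% and 89%. These shares may overstate power in the real libraries. There CG31219 (2.91) and CG14569 (-2.43) reached only an adjusted p of 0.141 in the limma fit. The absence of calls therefore does not exclude large changes. An exact permutation test of a single gene could not go below p = 0.1 with 3 against 3 libraries.

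The genes with the smallest unadjusted p did not pass and are given as values on the log2(TPM + 1) scale, which understates changes of low genes. CG31219 (FBgn0051219; arm 3R, 19651018 to 19652430 in BDGP6.54) had 0 reads in each control library and 199, 286 and 101 reads in the libraries of the other group, at least 70.8-fold higher by mean TPM against a floor of 3 reads per library. CR45605 averaged 0.327 ± 0.0936 TPM in controls and 7.72 ± 5.19 TPM in progeny of InR-DN mothers. The small heat shock protein gene Hsp23 averaged 29.7 ± 7.70 TPM in controls and 65.5 ± 18.4 TPM in progeny of InR-DN mothers. CG11034 averaged 10.7 ± 0.701 TPM in controls and 40.6 ± 18.5 TPM in progeny of InR-DN mothers. The remaining genes higher in progeny of InR-DN mothers had log2 fold changes of Rh50 (0.85), CG9259 (0.67), CG8534 (1.44), CG34301 (0.99), CG6271 (0.66), CR44386 (0.50), snoRNA:Or-CD1 (0.92), CR43889 (0.54). Among genes with lower means, CG14569 averaged 6.67 ± 1.32 TPM in controls and 0.451 ± 0.418 TPM in progeny of InR-DN mothers. Dro averaged 8.21 ± 1.09 TPM in controls and 3.12 ± 0.733 TPM in progeny of InR-DN mothers, and CecA1 averaged 8.12 ± 1.78 TPM in controls and 2.07 ± 0.871 TPM in progeny of InR-DN mothers; both encode antimicrobial peptides. CG30008 averaged 659 ± 46.9 TPM in controls and 415 ± 47.3 TPM in progeny of InR-DN mothers. The remaining genes lower in progeny of InR-DN mothers had log2 fold changes of CG3588 (-0.91), CG12766 (-0.76), CR45138 (-1.85), CG18179 (-1.04), snoRNA:Me28S-U3344b (-1.10), CG8964 (-1.26), CG13545 (-1.74), CG34267 (-2.25). Some of them rested on few reads. In InR-DN replicates 1 to 3 snoRNA:Me28S-U3344b had 5, 10 and 5 reads. At or near the floor of 3 reads there were CR45138 (2, 1 and 2 reads), CG13545 (2, 0 and 1) and CG34267 (4, 1 and 1). The groups did not overlap for any of these 24 genes, which their choice by the smallest p largely brings about and which is therefore no added evidence.

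Genes of antimicrobial peptides and the Imd pathway, the immune pathway that induces many of them, had the lowest camera p of the 35 lists tested. For members of this and all other lists, higher and lower means are means of log2(TPM + 1), which can differ in direction from mean TPM. Of 27 tested members, 23 had lower and 4 higher means in progeny of InR-DN mothers, with a median log2 fold change of -0.48 (camera, preset correlation, adjusted p = 6.7e-14). With an estimated correlation the call was lost (p = 0.0207, adjusted p = 0.427), and fry gave p = 0.0502. No member passed over all genes and 6 passed when adjusted over the list alone. Control replicate 3 stood apart for several members, with AttC at 61.8 TPM against 6.64 and 9.38 TPM in control replicates 1 and 2, DptB at 95.9 against 21.5 and 24.1 TPM, CecA2 at 10.9 against 2.43 and 1.93 TPM, Mtk at 80.1 against 14.9 and 13.0 TPM, and PGRP-SB1 at 51.2 against 10.9 and 11.3 TPM. The median of the list is the value of PGRP-SB1, whose InR-DN mean of 13.2 TPM lay above control replicates 1 and 2; without control replicate 3 the list had a median of -0.39 and still passed with the preset correlation. The members with higher means on the log2 scale were Drsl3 (0.54), Mtk (0.24), Drsl2 (0.20) and the transcription factor gene Rel (0.14). By mean TPM Mtk was lower in progeny of InR-DN mothers, at 29.9 TPM against 36.0 TPM in controls. Drs averaged 811 ± 84.8 TPM in controls and 519.9 ± 178 TPM in progeny of InR-DN mothers. Def averaged 86.0 ± 23.4 TPM in controls and 40.8 ± 10.6 TPM in progeny of InR-DN mothers. Dpt averaged 11.7 ± 0.404 TPM in controls and 5.89 ± 1.61 TPM in progeny of InR-DN mothers. CecC averaged 3.36 ± 0.673 TPM in controls and 0.671 ± 0.514 TPM in progeny of InR-DN mothers. Members near no difference included the pathway gene imd (-0.05) and the receptor gene PGRP-LE (-0.02). The oenocyte genes Cyp4g1 and eloF lay lower in the same group, each by a log2 fold change of -0.36 (adjusted p = 1.00). Their unadjusted limma p was 0.0271 for Cyp4g1 and 0.0127 for eloF, whose groups did not overlap. Within the InR-DN group Cyp4g1 and eloF did not move together. In InR-DN replicates 1 to 3 Cyp4g1 lay at 6425, 8996 and 7037 TPM, eloF at 340, 314 and 397 TPM and Drs at 421, 726 and 413 TPM. Thus eloF was lowest where the other 2 were highest. Drs, Def, Dpt, CecC, AttC, DptB, CecA2, Mtk, PGRP-SB1, Drsl2, Drsl3, imd, PGRP-LE and Rel were chosen after their values were seen.

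**Figure D2:**
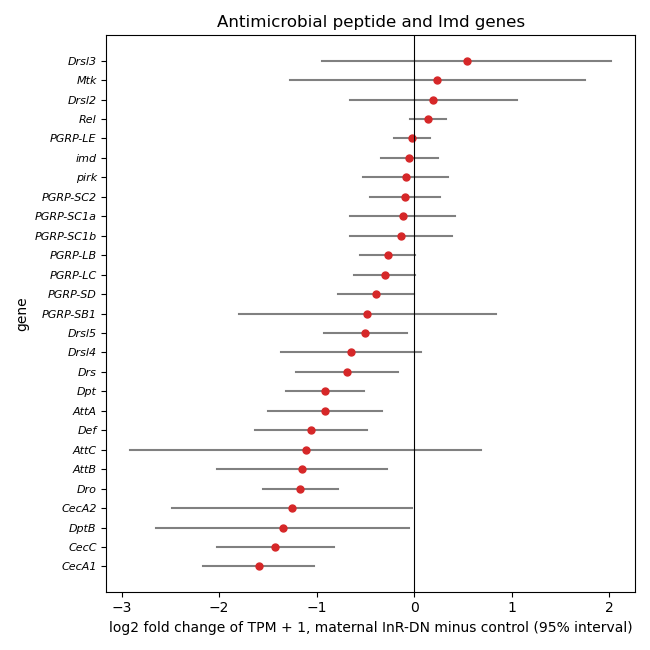
Log2 fold change of TPM + 1 (progeny of InR-DN mothers minus controls, horizontal axis) of the 27 tested antimicrobial peptide and Imd genes; points are limma estimates and lines their 95% confidence intervals, n = 3 per group. 23 of the 27 points lie below 0, the lowest being CecA1 at -1.59.

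Another 6 lists passed camera with the preset correlation, and each lost its call with an estimated correlation (adjusted p = 0.427 for heat shock proteins and 0.99 for the other 5). With the preset correlation every other split of the libraries into 3 against 3 called more lists, 12 to 20, than the 7 of the real split. Heat shock proteins had 12 tested members, 9 with a higher and 3 with a lower mean (median 0.15, camera adjusted p = 0.0146), and those with the smallest p were Hsp23 (1.11) and Hsp22 (0.48). Progenitor and Notch markers had 14 tested members, 4 with a higher and 10 with a lower mean (median -0.12, camera adjusted p = 0.0246), and those with the smallest p were mira (-0.37) and E(spl)malpha-BFM (-0.40). Lysozymes had 6 tested members, 1 with a higher and 5 with a lower mean (median -0.26, camera adjusted p = 0.0290), and those with the smallest p were LysP (-0.26) and LysE (-0.39). The vacuolar ATPase had 20 tested members, 2 with a higher and 18 with a lower mean (median -0.04, camera adjusted p = 0.0290), and those with the smallest p were VhaM8.9 (-0.09) and Vha13 (-0.07). The cell cycle list had 27 tested members, 27 with a higher and 0 with a lower mean (median 0.11, camera adjusted p = 0.0348), and those with the smallest p were ial (0.27) and cdc2 (0.23). The ovary and eggshell list had 17 tested members, 14 with a higher and 3 with a lower mean (median 0.60, camera adjusted p = 0.0481), and those with the smallest p were Vm32E (2.61) and Vm34Ca (1.55). Leaving out 1 library moved Hsp22 to 0.29 (InR-DN replicate 2), mira to -0.23 and E(spl)malpha-BFM to -0.15 (control replicate 1), LysE to -0.18 (InR-DN replicate 1), Vm32E to 4.08 and Vm34Ca to 2.61 (control replicate 2), and Vm32E to 1.49 and Vm34Ca to 0.34 (control replicate 3). The ovary and eggshell call was also lost with a pseudocount of 5, no filter, the 5 TPM filter, both rescalings and voom. The progenitor call was lost with the 5 TPM filter and quantile normalization, and the vacuolar ATPase call with no filter, the replicate block and voom. With no filter the heat shock median was 0.07. Hsp23 passed when adjusted over the list alone (1 member), and no member of the other 5 did. The most abundant ovary and eggshell members were osk at 787 TPM in controls and 806 TPM in the other group and Cp36 at 322 TPM in controls and 158 TPM in the other group, and the eggshell gene Cp36 ranged from 0.193 to 498 TPM over the 6 libraries. Heat shock proteins passed with the preset correlation when any 1 library was left out, with a median of 0.27 without control replicate 3 and 0.24 without InR-DN replicate 2. The progenitor list lost the call without control replicate 1 (median -0.02) or InR-DN replicate 3 (-0.10), and lysozymes lost it without control replicate 2 (-0.22), control replicate 3 (-0.27) or InR-DN replicate 1 (-0.06). The vacuolar ATPase lost it without control replicate 1 (-0.03), control replicate 2 (-0.04), InR-DN replicate 1 (-0.03) or InR-DN replicate 3 (-0.04), and had a median of -0.07 without control replicate 3. The ovary and eggshell median was 0.09 without control replicate 1, 0.20 without control replicate 3 and 0.25 without InR-DN replicate 2, where the call was lost, and 1.32 without control replicate 2 and 0.33 without InR-DN replicate 1, where it held. All 27 cell cycle genes had higher means, none with an unadjusted p under 0.05, and the named members did not divide by group. In control replicates 1 to 3 ial lay at 34.2, 30.6 and 45.9 TPM and cdc2 at 152, 136 and 181 TPM, and in InR-DN replicates 1 to 3 ial lay at 51.4, 33.2 and 49.6 TPM and cdc2 at 228, 139.8 and 189 TPM; both genes were lower in InR-DN replicate 2 than in control replicate 3. The cell cycle median was 0.26 without control replicate 3 and 0.30 without InR-DN replicate 2, and the call was lost without control replicate 1 (0.05), control replicate 2 (0.03), InR-DN replicate 1 (-0.04) or InR-DN replicate 3 (0.08).

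Digestion and metabolism lists were not called. Digestive serine proteases had 29 tested members, 13 with a higher and 16 with a lower mean (median -0.05, camera adjusted p = 0.567), and those with the smallest p were Jon25Biii (1.10) and Ser12 (-0.63). Carbohydrate digestion had 18 tested members, 10 with a higher and 8 with a lower mean (median 0.06, camera adjusted p = 0.979), and those with the smallest p were CG9463 (-1.62) and Amy-d (0.23). Lipid digestion and transport had 23 tested members, 14 with a higher and 9 with a lower mean (median 0.11, camera adjusted p = 0.352), and those with the smallest p were CG6271 (0.66) and LpR1 (-0.30). Lipogenesis and lipid storage had 21 tested members, 11 with a higher and 10 with a lower mean (median 0.01, camera adjusted p = 0.979), and those with the smallest p were v(2)k05816 (-0.38) and Lsd-2 (0.10). Fatty acid beta-oxidation had 14 tested members, 9 with a higher and 5 with a lower mean (median 0.03, camera adjusted p = 0.490), and those with the smallest p were yip2 (0.10) and CG6543 (-0.09). Glycolysis had 14 tested members, 9 with a higher and 5 with a lower mean (median 0.03, camera adjusted p = 0.490), and those with the smallest p were Hex-A (-0.12) and Gapdh2 (0.10). Glycogen, trehalose and gluconeogenesis had 11 tested members, 9 with a higher and 2 with a lower mean (median 0.10, camera adjusted p = 0.236), and those with the smallest p were Pepck (0.68) and fbp (0.19). TCA cycle had 19 tested members, 9 with a higher and 10 with a lower mean (median -0.01, camera adjusted p = 0.930), and those with the smallest p were Sucb (-0.09) and SdhC (0.13). Nuclear-encoded oxidative phosphorylation had 63 tested members, 40 with a higher and 23 with a lower mean (median 0.01, camera adjusted p = 0.332), and those with the smallest p were CG32230 (0.19) and CG9603 (-0.19). Jon25Biii, a digestive protease, averaged 442 ± 102 TPM in controls and 970.0 ± 327 TPM in progeny of InR-DN mothers. Without control replicate 3, where it lay at 29.7 TPM, CG9463 was at -0.99, and without InR-DN replicate 2 Pepck was at 0.36. Digestive serine proteases, carbohydrate digestion, the TCA cycle and oxidative phosphorylation were called higher without InR-DN replicate 1 and lower without InR-DN replicate 2, and digestive serine proteases also lower without InR-DN replicate 3. Lipid digestion, beta-oxidation and the glycogen list were called higher without InR-DN replicate 1, the glycogen list also higher without InR-DN replicate 3, and lipogenesis lower without InR-DN replicate 2. Mitochondrially encoded transcripts were not analysed here.

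The remaining lists of signalling, gut cell types and defence were not called either. Insulin and TOR signalling and FOXO targets had 23 tested members, 13 with a higher and 10 with a lower mean (median 0.0014, camera adjusted p = 0.666), and those with the smallest p were Ilp8 (0.53) and S6k (0.10). Enteroendocrine markers had 19 tested members, 5 with a higher and 14 with a lower mean (median -0.05, camera adjusted p = 0.171), and those with the smallest p were CCHa1 (-0.31) and AstC (-0.20). Enterocyte markers had 13 tested members, 5 with a higher and 8 with a lower mean (median -0.01, camera adjusted p = 0.844), and those with the smallest p were dve (-0.13) and Myo31DF (-0.07). Regenerative signalling had 11 tested members, 7 with a higher and 4 with a lower mean (median 0.01, camera adjusted p = 0.567), and those with the smallest p were upd3 (0.59) and vn (0.17). Glutathione S-transferases had 32 tested members, 18 with a higher and 14 with a lower mean (median 0.03, camera adjusted p = 0.476), and those with the smallest p were GstD2 (1.16) and GstS1 (0.27). Cytochrome P450 detoxification had 51 tested members, 31 with a higher and 20 with a lower mean (median 0.03, camera adjusted p = 0.396), and those with the smallest p were Cyp309a2 (0.52) and Cyp6a9 (0.61). Redox defence had 22 tested members, 16 with a higher and 6 with a lower mean (median 0.06, camera adjusted p = 0.0637), and those with the smallest p were ref(2)P (0.17) and Sod2 (0.12). Without InR-DN replicate 1 upd3 was at 0.34. Cytochrome P450 detoxification was called higher without InR-DN replicate 1 and lower without InR-DN replicate 2, glutathione S-transferases and redox defence higher without InR-DN replicate 1, and enteroendocrine markers lower without control replicate 3 or InR-DN replicate 2. With no filter redox defence was called higher and the Turandot list, then large enough to test, lower. The Turandot stress genes had 4 tested members, too few for the list test, all with lower means, and TotC lay at 766 TPM in control replicate 1 against 11.2 to 42.4 TPM in the other libraries. The log2 fold change of TotC was -1.44, 0.32 without control replicate 1 and -2.67 without control replicate 2, and that of TotM was -1.39, and -0.26 without control replicate 1, where TotM lay at 216 TPM against 11.7 to 30.4 TPM in the other libraries.

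The same held for the remaining cellular lists. Unfolded protein response and ER chaperones had 15 tested members, 7 with a higher and 8 with a lower mean (median -0.0018, camera adjusted p = 0.844), and those with the smallest p were Crc (-0.10) and Xbp1 (0.09). Polycomb and Trithorax group had 27 tested members, 17 with a higher and 10 with a lower mean (median 0.02, camera adjusted p = 0.879), and those with the smallest p were trx (-0.16) and ph-p (-0.19). Metallothioneins and metal handling had 16 tested members, 11 with a higher and 5 with a lower mean (median 0.03, camera adjusted p = 0.126), and those with the smallest p were MtnB (0.56) and MtnC (0.49). Peritrophic matrix and mucins had 14 tested members, 7 with a higher and 7 with a lower mean (median 0.01, camera adjusted p = 0.962), and those with the smallest p were Muc55B (-0.78) and Muc26B (-1.41). Cytosolic ribosomal proteins had 87 tested members, 27 with a higher and 60 with a lower mean (median -0.02, camera adjusted p = 0.439), and those with the smallest p were RpS19b (0.35) and RpL23 (-0.12). Without InR-DN replicate 2 MtnC was at 0.28. Ribosomal proteins were called higher without InR-DN replicate 1 and lower without InR-DN replicate 2, the Polycomb list the other way round, and metallothioneins higher without control replicate 1, InR-DN replicate 1 or InR-DN replicate 3. Muc55B passed when adjusted over the peritrophic list alone (1 member).

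Lists of other tissues, fixed before the data were examined, were not called apart from the ovary and eggshell list. Visceral muscle had 19 tested members, 5 with a higher and 14 with a lower mean (median -0.05, camera adjusted p = 0.368), and those with the smallest p were Mlp60A (0.18) and sls (-0.23). Fat body and yolk proteins had 7 tested members, 4 with a higher and 3 with a lower mean (median 0.05, camera adjusted p = 0.834), and those with the smallest p were fit (0.52) and to (-0.23). Malpighian tubule had 13 tested members, 3 with a higher and 10 with a lower mean (median -0.07, camera adjusted p = 0.185), and those with the smallest p were Drip (-0.17) and tsh (-0.25). Dosage compensation and sex had 6 tested members, 1 with a higher and 5 with a lower mean (median -0.05, camera adjusted p = 0.236), and those with the smallest p were roX1 (-0.94) and msl-2 (-0.14). Hemocyte had 10 tested members, 7 with a higher and 3 with a lower mean (median 0.02, camera adjusted p = 0.831), and those with the smallest p were Pxn (-0.23) and He (0.67). Trachea had 8 tested members, 4 with a higher and 4 with a lower mean (median -0.03, camera adjusted p = 0.979), and those with the smallest p were Gasp (0.59) and obst-A (1.05). Neuron had 9 tested members, 0 with a higher and 9 with a lower mean (median -0.04, camera adjusted p = 0.396), and those with the smallest p were elav (-0.16) and nSyb (-0.06). Without control replicate 3, visceral muscle (adjusted p = 0.00229) and Malpighian tubule (0.00110) were called lower; without InR-DN replicate 2 both were called lower (0.0410 and 0.0131) and trachea higher (0.0305). Leaving out 1 library moved roX1 to -0.36 (control replicate 1, where it lay at 13.7 TPM) and -1.51 (control replicate 3), fit to 0.34 (control replicate 2), He to 0.38 (InR-DN replicate 3), Gasp to 0.98 (InR-DN replicate 2) and 0.37 (InR-DN replicate 3), and obst-A to 0.62 (InR-DN replicate 1) and 1.84 (InR-DN replicate 2). The most abundant visceral muscle genes were Act57B at 868 TPM in controls and 915 TPM in the other group and Mlc2 at 385 TPM in controls and 379.7 TPM in the other group. The most abundant fat body and yolk proteins genes were Yp1 at 8461 TPM in controls and 7213 TPM in the other group and Yp3 at 3259.8 TPM in controls and 3386 TPM in the other group. The most abundant Malpighian tubule genes were Uro at 95.5 TPM in controls and 102 TPM in the other group and salt at 78.4 TPM in controls and 74.8 TPM in the other group. The most abundant dosage compensation and sex genes were Sxl at 66.8 TPM in controls and 65.5 TPM in the other group and tra at 30.0 TPM in controls and 30.2 TPM in the other group. The most abundant hemocyte genes were Cg25C at 133 TPM in controls and 135 TPM in the other group and vkg at 93.0 TPM in controls and 93.4 TPM in the other group. The most abundant trachea genes were Gasp at 21.2 TPM in controls and 34.7 TPM in the other group and verm at 18.8 TPM in controls and 22.1 TPM in the other group. The most abundant neuron genes were nSyb at 48.6 TPM in controls and 46.5 TPM in the other group and Syx1A at 45.0 TPM in controls and 44.6 TPM in the other group. The testis and accessory gland list had 2 tested members, bol (0.02) and janB (0.06), with control means of 13.5 TPM for bol and 7.51 TPM for janB.

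Median, mean and camera direction did not all share a sign for these lists, none of them called: digestive serine proteases, carbohydrate digestion, lipogenesis and lipid storage, TCA cycle, peritrophic matrix and mucins, trachea.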

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

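The voom fit was chosen after seeing the data. The count of genes past the threshold stayed at 0 under 8 of the settings chosen before the data were examined, the replicate block among them, and was 1 with a pseudocount of 0.1 and 1 in voom on recovered reads (CG31219 in both), where the count at 2-fold was 1 as well. Leaving out 1 library gave 0 to 3 genes, and 0 to 3 at 2-fold: Obp19c without control replicate 1, CG34267, CG13705 and CG33272 without control replicate 2, CG11034 without InR-DN replicate 1 and CG31219 without InR-DN replicate 3. The cause was not tested. InR kept its direction throughout.

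The number of lists called was 7, and was 0 with an estimated correlation and 0 in fry. It was 6 with a pseudocount of 5, median-of-ratios rescaling or the replicate block, and 5 with the 5 TPM filter, quantile normalization or voom. Ovary and eggshell lost the call with a pseudocount of 5 (adjusted p = 0.0638), no filter (0.0521), the 5 TPM filter (0.0807), median-of-ratios rescaling (0.0812), quantile normalization (0.0903) and voom (0.0648). The progenitor list lost it with the 5 TPM filter (0.137) and quantile normalization (0.0581), and the vacuolar ATPase with no filter (0.109), the replicate block (0.0568) and voom (0.0648). With no filter 2 others were called, Turandot (0.0381) and redox defence (0.0425). Leaving out 1 library gave 4 to 18 lists, with 4 without control replicate 1, 4 without control replicate 2, 17 without InR-DN replicate 1 and 18 without InR-DN replicate 2. The antimicrobial list passed with the preset correlation in every such fit, with medians of -0.52 to -0.38.

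With the replicate block, 0 genes passed. The numbers did not pair the libraries: deviations of same-numbered libraries correlated across genes at -0.41 to -0.13, and 0 of 6 libraries correlated best with its own number.

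None of the genes that changed sign had passed. With quantile normalization osk was 0, tra 0, Cg25C -0.01 and vkg -0.02. When 1 library was left out, the log2 fold change ran from -0.01 to 0.16 for Act57B, from -0.04 to 0.08 for Cg25C, from -4 to 0.79 for Cp36, from -0.1 to 0.03 for Mlc2, from -0.09 to 0.02 for Sxl, from -0.09 to 0.05 for Syx1A, from -2.67 to 0.32 for TotC, from -0.09 to 0.2 for Uro, from -0.03 to 0.12 for Yp3, from -0.06 to 0.08 for bol, from -0.04 to 0.16 for janB, from -0.02 to 0.08 for osk, from -0.19 to 0.05 for salt, from -0.03 to 0.05 for tra, from -0.28 to 0.68 for verm, from -0.04 to 0.08 for vkg, from -0.04 to 0.3 for the median of the cell cycle list. The edgeR and DESeq2 fits listed as alternatives were not run; limma voom was the one fit of the recovered reads. Depth limits genes of few reads.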

Other observations

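All tests of explanations in this part were chosen after the result they measure was seen, except the planned test of genomic position. Some eggshell and cuticle genes, chosen after their values were seen, varied strongly within groups. The eggshell gene Cp38 lay at 0.0431, 290.0 and 364 TPM in the controls and at 456, 28.3 and 0.499 TPM in the other group. The cuticle gene Cpr65Ea lay at 0.200, 61.8 and 0.319 TPM in the controls and at 139, 6.04 and 89.8 TPM in the other group.

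The libraries labelled intestine held transcripts of the eye, antenna, flight muscle, oenocytes and ovary. Ovary, fat body or tubule carried along in dissection cannot bring photoreceptor RNA, and ninaE was at 2249 TPM or more in every library, which argues against these organs as the whole source. One mixed or mislabelled library is argued against by the highest ninaE being 1.34 times the lowest. Under the hypothesis that the RNA came from whole adult females or from several body parts, such markers should be present throughout, and 100% of 33 markers were at 1 TPM or more in all 6 libraries, while testis and accessory gland genes had a median of 0.07 TPM; the markers were picked with part of these values known, so this may describe the samples but does not establish it. How the RNA or the table came to differ from the labels was not tested, and no biological explanation was tested; differences between the groups may then arise outside the gut.

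Antimicrobial peptide and Imd genes had lower means in progeny of InR-DN mothers, with 12 of 27 at an unadjusted p under 0.05. A smaller share of fat body in that group would lower fat body genes alike. The 7 tested fat body and yolk genes had a median of 0.05 with a median absolute deviation of 0.41, against -0.48 for the list. That median is the value of the yolk gene Yp3, and the yolk genes are also expressed in the ovary. Of the 7 genes, 4 had higher and 3 lower means, among them fit (0.52) and to (-0.23). A smaller share of fat body therefore stays open. The oenocyte genes Cyp4g1 and eloF had lower group means (-0.36 each), but eloF was lowest in InR-DN replicate 2, where Cyp4g1 and Drs were highest in that group, which leaves a smaller share of another tissue open. Of the 10 splits of the libraries, 1 gave as many members, the real one, and the highest other split gave 6. The list was singled out by its camera p in the real split, so this count favours that split. The absolute median of the list was 0.479 in the real split and 0.436 and 0.402 in a pair of others. With 10 splits the share cannot go below 0.1. The maternal genotype, a transgene inherited by the progeny and differences in infection or housing, untested here, stay open.

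A set of 11 genes had reads at least 5-fold apart between every library of one group and every library of the other, with at least 10 reads in each higher library; 2 were higher and 9 lower in progeny of InR-DN mothers. For CG31219, depth is argued against by 661 control reads expected at the rate of the other group, where 0 were seen. An inherited chromosome or strain variant may be a source: 6 of the genes lie on 3L, but counted as 8 loci no arm stood out (smallest Fisher's exact adjusted p = 0.826), which leaves it open. Among the controls, all the lower genes except CG14569 and CR45138 had their lowest TPM in replicate 2. CG13705, chosen after its values were seen, lay at 14.2, 2.43 and 24.8 TPM in control replicates 1 to 3. The loci may therefore not be independent, and the source of this shared variation was not tested. Such genes were as many in 3 of the 10 splits, the real one included, and the highest other split had 41; 10 splits are too few for a share under 0.05. The maternal genotype stays open as well, untested.

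In the planned test of genomic position no gene had passed, so the 341 genes with an unadjusted p under 0.05 were used. The share on no arm passed the test (smallest Fisher's exact adjusted p = 0.756). The nearest tested neighbour was also in the set for 15.2%, against a median of 2.93% in 100000 resamples (permutation p = 1e-05, the smallest these can give), but equally large sets from the other 9 splits gave 7.33% to 18.8%.

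For the count of genes, the real split gave 0 and the highest other split 41; every split reaches 0, so this count tests nothing. For the count of lists, the real split gave 7, the fewest of the 10, and the others gave 12 to 20. Calls with the preset correlation thus arose in every split, and their number does not set the real split apart. Splits are too few here for a share under 0.05. Some splits point to structures of the samples other than their group. The split of control replicates 1 and 2 with InR-DN replicate 2 against the rest gave 3370 genes at an unadjusted p under 0.05, against 341 in the real split, though 0 past the adjusted p. The split with 41 genes past it (control replicates 1 and 3 with InR-DN replicate 2 against the rest) gave 382.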
